A study of Homo sapiens with 6 samples.

How the data were processed

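The study measured messenger RNA of the human ovarian carcinoma line A2780 in 6 libraries, 3 from cells treated with the BPP peptide and 3 controls. Per the labels' protocols, total RNA was extracted with TRIzol and made into strand-specific mRNA libraries. Per the submitters' processing notes, Trimmomatic 0.36, featureCounts, Subread 1.5.1 and edgeR 3.12.1 were used. The aligner and the strand setting of the counting are not given in the sources used here. The same notes name the mouse build mm10, but chromosomes, positions and symbols of the deposited table are those of human build GRCh38, and the coordinates printed here are on that build.

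The authors deposited 1 table of RPKM (reads per kilobase of exon, scaled to the reads assigned in each library) for 43633 genes, with each gene's exon positions and summed exon length. Multiplying a value by the gene length and dividing by the value of 1 read gave a whole number within 0.001 for 100% of 188262 values above 0. The recovered reads sum to the total the values were divided by, which gives depths of 58199906 to 62299769 reads per library. In a gene of 1 kilobase, 1 read is worth 0.0161 to 0.0172 RPKM. RPKM corrects for total reads and gene length only, so a change in a few abundant genes would shift all others slightly. Gene names were matched to GENCODE release 29 for 98% of genes by name and overlap or by exact position, and 28 names that a spreadsheet had turned into dates were resolved by position.

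Groups and replicate numbers came from the sample titles. Replicates of a group differed by more than sampling noise (chi-square per gene 3.36 to 7.65 between pairs), so no library was counted as a duplicate. The samples, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The planned count test applied only to a table of counts, so the planned RPKM test was used. Values were tested as log2(RPKM + 1) with limma 3.58.1 (robust empirical Bayes with a mean-variance trend, statmod 1.5.0, R 4.3.3), on genes at 1 RPKM or more in at least 3 of the 6 libraries. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 changes are on the log2(RPKM + 1) scale, apart from those with voom. Unless said otherwise, folds and percent changes are ratios of mean RPKM, and ± is the SD over 3 libraries.

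Gene lists were tested with camera on the moderated statistics, with a preset correlation of 0.01 between genes. Of 34 lists, 30 had 5 or more tested members and were adjusted together. Camera with an estimated correlation between genes was run beside it, and none of the 10 calls passed with it. The genes named are the 12 protein-coding genes with the largest rise and the 12 with the largest fall among those past the threshold, with no overlap between groups and a higher mean of at least 1 RPKM, together with the 3 genes of the series title and up to 4 members with the smallest p in each list. Other names are said to be chosen after their values were seen, and some genes that this rule takes are not reported here. Single values were compared with exact permutation tests, and intervals of read counts are exact Poisson intervals at 95%. These cover counting error only, since PCR copies are not independent molecules.

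The test was tried on simulated data for BPP versus control with 13982 genes tested and 200 genes changed 1.25-fold or 1.5-fold, besides a planted set changed by less. It called 62.9% of genes changed 1.25-fold and 90.8% of genes changed 1.5-fold, with 9 false calls among 160 and 0 in the wrong direction. All simulated genes had the same replicate spread beyond counting noise (dispersion 0.00164, the median of genes with many reads). Genes of larger spread were thus simulated too quietly, and the real test may do worse. Other settings fixed in advance were a replicate block, leaving out each library, median-ratio rescaling, quantile normalization, no filter, a filter of 5 RPKM, a pseudocount of 0.1, no variance trend, leaving out mitochondrial and ribosomal-protein genes, and for lists camera with an estimated correlation and fry. Settings added after seeing the data were voom on the recovered reads at both scalings and protein-coding genes only. The voom settings used genes with at least 10 reads in at least 3 libraries. Another added setting, the correction for GC content and gene length, removed each library's trend with GC content, gene length and mean expression, fitted together. Mitochondrial RNA processing factors and pentose phosphate genes were added as lists at the same stage. Enrichment of annotated terms was not run, since the table annotates no terms. Python libraries were numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.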

Results

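RNA was sequenced from A2780 cells, an established human ovarian carcinoma line, after treatment with BPP, a peptide designed to compete for a phosphorylation site of BIN2, or from control cells. BIN2 (bridging integrator 2) is a membrane-binding protein of the BAR-domain family. The series design names a TAT peptide, a cell-penetrating carrier sequence, as the comparison, and the libraries themselves are labelled only as control. There were 3 control and 3 BPP libraries, and neither the dose nor the time of treatment is given in the sources used here. Reads assigned to genes numbered 62082014, 59777192 and 62203893 in the control libraries and 59688607, 62299769 and 58199906 in the BPP libraries, so depth was similar in both groups. Libraries of the same group correlated more closely across genes (Pearson r of log2 values from 0.9957 to 0.9966) than libraries of different groups (0.9911 to 0.9928), and the first principal component, with 50.3% of the variance, separated BPP from control. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

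The first comparison asked whether the messages of the genes named in the title of the series differed, since the peptide is aimed at a protein and RNA does not measure phosphorylation. HDAC1, a class I histone deacetylase, was 10.2% lower in BPP, at 68.7 ± 1.54 RPKM (SD, n = 3) against 76.5 ± 0.652 RPKM in control (n = 3). This fall was small but larger than the spread between replicates (log2 fold change −0.15, SE 0.029, limma adjusted p = 0.0118), with all 3 BPP libraries below all 3 control libraries. RPS6, a protein of the small ribosomal subunit, stood at 279 ± 7.78 RPKM in BPP and 281 ± 5.83 RPKM in control (n = 3 each), a difference within the replicate spread (log2 fold change −0.009, limma adjusted p = 0.872). BIN2 itself was barely represented, with 0.0666 ± 0.0179 RPKM in BPP and 0.0865 ± 0.0296 RPKM in control (n = 3 each). The BIN2 values correspond to 12, 16 and 20 reads in the BPP libraries and 30, 16 and 18 reads in the control libraries, and 53.6% of all listed genes had a higher mean. Summed over each group, 48 reads (95% exact Poisson interval 35.4 to 63.6) stood against 64 reads (49.3 to 81.7), overlapping intervals that cover counting error only, and no difference was detectable at this depth. With voom on the recovered reads, a setting added after seeing the data, BIN2 did not pass (log2 fold change −0.35, SE 0.39, limma adjusted p = 0.576; 0.552 to 0.688 over the settings that tested it). A two-sided exact permutation test gave p = 0.4, but 0.1 is the smallest value 3 against 3 libraries allow, so that test could not pass 0.05. Its relatives BIN1 and BIN3, chosen after their values were seen, were better expressed, BIN1 at 8.8 ± 0.208 against 9.17 ± 0.245 RPKM and BIN3 at 4.97 ± 0.319 against 5.33 ± 0.25 RPKM in BPP and control. On human genome build GRCh38, HDAC1 lies on chromosome 1 from 32292086 to 32333635, RPS6 on chromosome 9 from 19375715 to 19380254 and BIN2 on chromosome 12 from 51281038 to 51324668, and the values count reads over each gene's exons. Of the pair that could be tested, 1 gene, HDAC1, passed both over all genes and adjusted over the list alone, and its adjusted p rose to 0.0551 when no filter on low genes was applied.

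**Figure D1:**
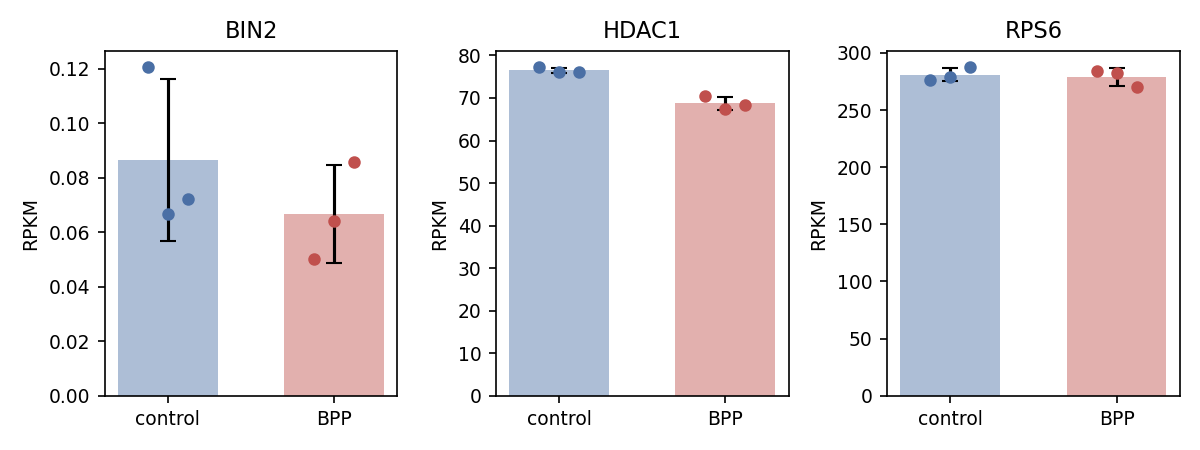
RPKM of BIN2, HDAC1 and RPS6 in control and BPP libraries, with a separate axis from 0 for each gene. Points are the 3 libraries of a group, bars their mean and whiskers the SD; HDAC1 is lower in all 3 BPP libraries, while the groups overlap for BIN2 and RPS6.

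The second comparison covered all genes. BPP and control cells differed in many messages, mostly by small amounts. Of 14004 genes tested, 3033 (21.7%) passed the limma test at an adjusted p of 0.05, 1602 higher and 1431 lower in BPP. The median fold among these was 1.18 for genes that rose and 0.82 for genes that fell. A ratio of mean RPKM of 1.5 or more was reached by 87 risen and 167 fallen genes, and one of 2 or more by 12 and 25. On the log2(RPKM + 1) scale of the test, which understates changes of low genes, 7 genes changed by 2-fold or more. The 3 values of one group lay entirely above or below those of the other in 5960 genes (42.6%), where chance gives 10%. Without a filter on low genes the count was 852 of 40021. Leaving out any single library, and so testing fewer samples, lowered the main count. It was 2485, 2013 and 1851 without control replicate 1, 2 and 3. Without BPP replicate 1, 2 and 3 it was 1646, 2025 and 1707.

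The 12 protein-coding genes with the largest falls dropped to between 0.192 and 0.569 of their control RPKM. PLA2G3, a secreted phospholipase A2 (chromosome 22, 31134809 to 31140607), fell from 8.01 ± 0.0586 to 3.69 ± 0.243 RPKM (n = 3 each, log2 fold change −0.94, SE 0.045, limma adjusted p = 0.000193). SLC30A8, a zinc transporter (chromosome 8, 116950273 to 117176714), fell from 9.98 ± 0.127 to 4.83 ± 0.229 RPKM (log2 fold change −0.91). ANGPTL4, a secreted inhibitor of lipoprotein lipase (chromosome 19, 8363289 to 8374373), fell from 9.15 ± 1.17 to 4.38 ± 0.397 RPKM. SCD, the stearoyl-CoA desaturase (chromosome 10, 100347124 to 100364834), was the most abundant of this group and fell from 86.7 ± 2.54 to 49.3 ± 1.91 RPKM. THRSP, a regulator of lipid synthesis, fell from 1.29 ± 0.0938 to 0.248 ± 0.102 RPKM, and NUPR1, a stress-responsive nuclear protein, from 1.93 ± 0.14 to 0.699 ± 0.0854 RPKM. ISM2, NCOA5, PPP1R3C, FADS2, BHLHE40 and SPRY2 also fell, with BPP at 0.457, 0.515, 0.483, 0.521, 0.516 and 0.568 of the control RPKM.

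The 12 protein-coding genes with the largest rises changed by smaller amounts on the log2(RPKM + 1) scale than the 12 with the largest falls. CREB3L3, a membrane-bound transcription factor of liver and intestine (chromosome 19, 4153601 to 4173054), rose from 3.97 ± 0.32 to 7.14 ± 1.52 RPKM (n = 3 each, log2 fold change 0.70, SE 0.14, limma adjusted p = 0.0171), a call that was lost without control replicate 2 (adjusted p = 0.0544), without BPP replicate 1 (0.0583) and without a filter on low genes (0.0723). HLA-DMB, a chaperone of class II antigen presentation (chromosome 6, 32934629 to 32941070), rose from 1.33 ± 0.0328 to 2.53 ± 0.13 RPKM (log2 fold change 0.60, adjusted p = 0.000626). DRC1, a component of motile cilia, rose from 3.87 ± 0.0783 to 6.23 ± 0.486 RPKM, CCDC186 from 7.6 ± 0.338 to 11.6 ± 0.916 RPKM, and ID3, an inhibitor of basic helix-loop-helix transcription factors, from 2.58 ± 0.301 to 4.15 ± 0.213 RPKM. HCST and ZNF805 rose 1.79-fold and 1.87-fold. FAM72B, FAM72C and FAM72D (1.53-fold, 1.51-fold and 1.49-fold) and ANKRD36 and ANKRD36B (1.55-fold and 1.52-fold) belong to families of near-identical copies that can share reads, so their single values are uncertain.

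**Figure D2:**
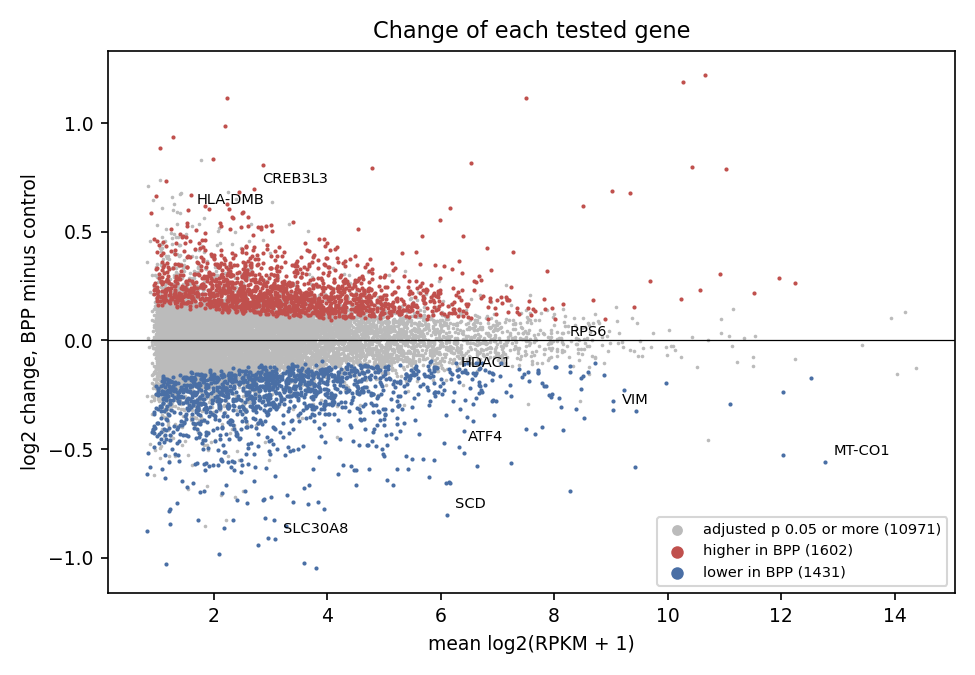
Change of each of the 14004 tested genes (log2 of RPKM + 1, BPP minus control) against its mean log2(RPKM + 1). Red points are the 1602 genes higher and blue points the 1431 genes lower in BPP at adjusted p 0.05, grey points the rest; most coloured points lie within 1 log2 unit of the zero line.

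Genes of lipid synthesis fell together. Of 32 tested members of the sterol and lipid synthesis list, 25 fell and none rose (26 fell adjusted over the list alone), with a median change of −20.2% (camera adjusted p = 3.74e-16; adjusted p = 0.406 with an estimated correlation). FDPS, the farnesyl diphosphate synthase of the sterol pathway, fell from 52.5 ± 0.87 to 35.7 ± 0.927 RPKM, and ACLY, which makes cytosolic acetyl-CoA, from 37.9 ± 0.867 to 26.9 ± 0.238 RPKM (n = 3 each). SCD, FADS1 and FADS2 are desaturases of fatty acids rather than sterol enzymes. FADS1 fell from 26.8 ± 0.672 to 16.5 ± 0.73 RPKM, and it shares 490 exonic bases with FADS2 on the opposite strand.

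Hypoxia-inducible and glycolytic genes also fell. Of 26 tested targets of hypoxia-inducible factors, 21 fell and none rose (23 fell adjusted over the list alone), with a median change of −29.6% (camera adjusted p = 7.34e-16; adjusted p = 0.406 with an estimated correlation). VEGFA, the endothelial growth factor, fell from 6.92 ± 0.242 to 4.29 ± 0.0556 RPKM, EGLN1, an oxygen-sensing prolyl hydroxylase, from 9.18 ± 0.628 to 6.19 ± 0.175 RPKM, and BHLHE40, a hypoxia-inducible repressor, from 8.55 ± 0.636 to 4.42 ± 0.353 RPKM (n = 3 each). Among 21 glycolytic enzymes and transporters, 16 fell and none rose (17 fell adjusted over the list alone), with a median change of −13.1% (camera adjusted p = 1.99e-08; adjusted p = 0.525 with an estimated correlation). ALDOC, an aldolase, fell from 16.1 ± 1.02 to 10.8 ± 0.52 RPKM, PGAM1 from 88.6 ± 3.33 to 71.1 ± 1.82 RPKM and ENO1, the main enolase, from 270 ± 10.1 to 227 ± 3.18 RPKM. The lactate exporter SLC16A3 fell from 2.15 ± 0.0295 to 1.59 ± 0.0195 RPKM. These lists share 3 tested genes.

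Targets of the stress transcription factors ATF4 and CHOP fell as well, 21 of 34 tested with none higher (24 fell adjusted over the list alone). Their median change was −18.1% (camera adjusted p = 2.82e-13; adjusted p = 0.406 with an estimated correlation). ATF4 itself fell from 92.7 ± 3.29 to 65.6 ± 1.34 RPKM, PSAT1, an enzyme of serine synthesis, from 44.4 ± 2.39 to 29.1 ± 1.39 RPKM, and DDIT4, an inhibitor of mTORC1 signalling, from 39.7 ± 1.87 to 25 ± 0.711 RPKM (n = 3 each). Of 30 immediate-early and serum-response genes, 16 fell and none rose (18 fell and 2 rose adjusted over the list alone), with a median change of −18% (camera adjusted p = 1.99e-08; adjusted p = 0.451 with an estimated correlation). The feedback inhibitors of growth factor signalling SPRY1, SPRY2 and SPRY4 were at 0.699, 0.568 and 0.617 of their control RPKM, and the transcription factor MYC fell from 4.21 ± 0.173 to 2.56 ± 0.209 RPKM.

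In the lists for mitosis, homologous recombination and DNA replication more genes rose than fell, by small amounts, and most members did not pass the test. Of 56 mitotic genes, 23 rose and none fell (27 rose and 1 fell adjusted over the list alone), with a median change of 7.77% (camera adjusted p = 4.59e-06; adjusted p = 0.406 with an estimated correlation). HJURP, a chaperone of centromeric histone, rose from 21 ± 0.33 to 25.9 ± 0.394 RPKM, the kinesin KIF2C from 40.4 ± 0.525 to 47.2 ± 0.494 RPKM, and DLGAP5 and SPC24, which act at the mitotic spindle and the kinetochore, 1.15-fold and 1.2-fold. In the homologous recombination list 9 of 36 genes rose and none fell, with the same count adjusted over the list alone (median change 7.54%, camera adjusted p = 0.00147; adjusted p = 0.525 with an estimated correlation). MRE11A rose from 13.3 ± 0.138 to 16 ± 0.232 RPKM (n = 3 each). ETAA1 and RAD54B rose 1.17-fold and 1.21-fold, the latter not past the threshold without a filter on low genes (limma adjusted p = 0.0561). Of 55 DNA replication genes, 15 rose and 3 fell (18 and 3 adjusted over the list alone), with a median change of 4.81% (camera adjusted p = 0.0258; adjusted p = 0.635 with an estimated correlation). RFC4, a clamp loader subunit, rose from 13.5 ± 0.541 to 17.3 ± 0.646 RPKM and CLSPN, a checkpoint mediator, from 23.7 ± 0.958 to 29.6 ± 0.786 RPKM, with POLD1 and POLD3 up 1.17-fold and 1.21-fold. The call of the replication list was lost without control replicate 3 (adjusted p = 0.0869), BPP replicate 1 (0.0565) or BPP replicate 2 (0.0995), and with a filter of 5 RPKM (0.175, the highest of its camera values with the preset correlation), and fry gave an adjusted p of 0.0652.

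**Figure D3:**
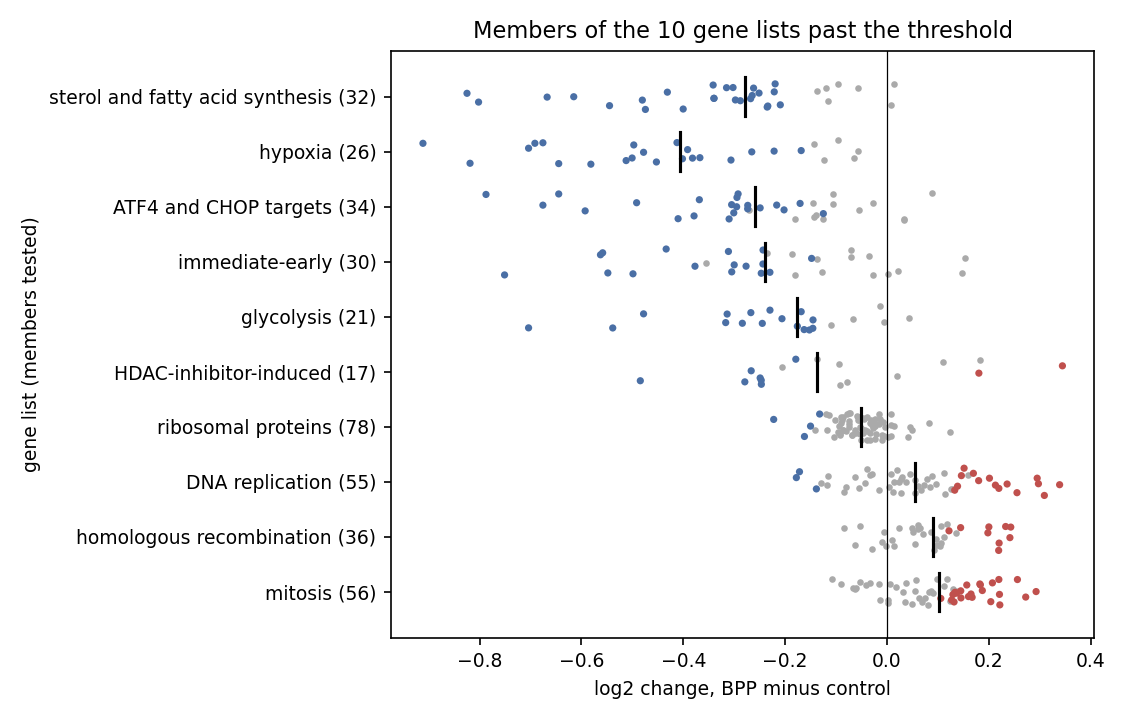
Log2 change (BPP minus control, log2 of RPKM + 1) of each tested member of the 10 gene lists past adjusted p 0.05 in the camera test. Blue and red points are members lower and higher in BPP at adjusted p 0.05, grey points the others, black bars the medians; in the sterol and lipid synthesis list 25 of 32 members are blue and in the mitosis list 23 of 56 are red.

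Gene groups related to HDAC1 and RPS6 were examined next. Among 17 genes commonly induced by HDAC inhibitors, 7 fell and 2 rose (10 and 4 adjusted over the list alone), with a median change of −9.77% (camera adjusted p = 0.0305; adjusted p = 0.406 with an estimated correlation). SAT1, a polyamine-catabolic enzyme, rose from 51.5 ± 1.27 to 65.7 ± 1.45 RPKM, whereas the linker histones HIST1H1C and H1F0 fell from 24.6 ± 0.738 to 20.5 ± 0.419 RPKM and from 80.8 ± 4.43 to 66.4 ± 2.78 RPKM. Without a filter on low genes H1F0 lost its call (limma adjusted p = 0.0589). The call of the list was lost without BPP replicate 2 (adjusted p = 0.0738, the highest of its camera values with the preset correlation). It was also lost after correction for GC content, gene length and mean expression (0.0573). Class I deacetylases and their complexes gave 3 higher and 5 lower of 37 (camera adjusted p = 0.175, but 0.0462 with voom on median-ratio scaled reads and 0.0489 with fry), where the corepressor RCOR2 fell from 26.2 ± 0.809 to 17 ± 0.855 RPKM. Of 78 ribosomal protein genes, 4 fell and none rose (1 fell adjusted over the list alone), and the list as a whole lay 3.44% lower by its median (camera adjusted p = 0.000218; adjusted p = 0.635 with an estimated correlation and 0.225 with fry). The 4 were RPL10, RPL28, RPLP0 and RPL10A, at 0.843, 0.898, 0.894 and 0.912 of control, and they kept their calls in 16, 11, 8 and 7 of 17 alternative settings. The calls of RPLP0 and RPL10A were thus lost in most of them. Ribosomal protein genes have many processed pseudogenes that can take up reads, so these values are uncertain.

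The lists for translation factors (4 higher and 6 lower of 38, camera adjusted p = 0.395), mTOR and S6 kinase signalling (3 and 5 of 36, 0.395) and ribosome biogenesis (9 and 8 of 55, 0.533) did not pass. Within them UBTF, a factor of ribosomal RNA transcription, fell from 41.2 ± 0.675 to 31.9 ± 0.775 RPKM, and EIF4G2 from 41.2 ± 2.11 to 33.3 ± 1.39 RPKM (n = 3 each). The BAR-domain and endocytosis list, to which BIN2 is related, had 4 higher and 3 lower of 37 (camera adjusted p = 0.618). Targets of p53 had 2 higher and 6 lower of 28 (0.395), apoptosis genes 3 and 4 of 34 (0.175), interferon-stimulated genes 6 and 8 of 38 (0.271) and NF-kB targets 1 and 3 of 16 (0.175). FAS, a death receptor, fell from 16.5 ± 0.217 to 13.3 ± 0.508 RPKM, and it shares 380 exonic bases with the more abundant ACTA2. Endoplasmic reticulum chaperones had 3 higher and 3 lower of 29 (0.175, but 0.0387 without a filter on low genes), with HSPA5 up from 237 ± 5.17 to 263 ± 6.74 RPKM, a call that was lost without BPP replicate 1 (limma adjusted p = 0.0589), without BPP replicate 3 (0.0537) and without the filter (0.075). Cytosolic heat-shock genes had 3 and 8 of 28 (0.259, but 0.0462 with voom on median-ratio scaled reads and 0.0164 with fry), with HSPA8 down from 324 ± 3.43 to 244 ± 13.3 RPKM.

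Further lists that did not pass in the main test were nuclear-encoded respiratory chain subunits (4 higher and 2 lower of 75, camera adjusted p = 0.874), lysosome and autophagy genes (6 and 5 of 47, 0.874) and NRF2 targets with metallothioneins (1 and 5 of 20, 0.175). TXNRD1, a thioredoxin reductase, rose from 90.2 ± 0.946 to 111 ± 2.69 RPKM (n = 3 each). Mesenchymal and matrix genes had 5 higher and 8 lower of 31 (0.139). This list passed without a filter on low genes (0.0352), with voom at both scalings (0.0343 and 0.0271) and with fry (0.0374). VIM, the intermediate filament vimentin, fell from 586 ± 15.2 to 469 ± 13.1 RPKM. YAP and TGF-beta targets had 4 higher and 6 lower of 22 (0.207, but 0.00455 with a filter of 5 RPKM), where ANKRD1 fell from 99.8 ± 3.23 to 69.4 ± 4.11 RPKM. Replication-dependent histones had 0 of 6 past the threshold (camera adjusted p = 0.199). Ovarian tumour markers had 1 lower of 5 (0.175, but 0.0271 without control replicate 1), while 22 of the 27 listed lay below 1 RPKM in both groups. Nuclear-retained and small RNAs had 1 higher and 1 lower of 12 (0.513).

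Most markers of other cell types lay below the filter on low genes. Of 26 blood cell genes, a list of leukocyte markers and haemoglobin genes, 4 were expressed enough to test (CD68, NKG7, HBB and HBA2), of 16 granulosa genes 1 and of 16 stromal or endothelial genes 3, too few for a test of the list. CD68, a lysosomal protein of macrophages that also occurs in other cells, rose from 14 ± 0.394 to 19 ± 0.29 RPKM (limma adjusted p = 0.000626). CD68 shares 1789 exonic bases with a read-through transcript on the same strand, so its value is uncertain. FOXL2, a granulosa transcription factor, stood at 2.18 ± 0.0968 and 2.2 ± 0.182 RPKM in BPP and control. COL3A1, a fibrillar collagen in both the stromal and the mesenchymal list, fell from 110.3 ± 2.92 to 95.2 ± 1.45 RPKM (n = 3 each, limma adjusted p = 0.00502), while the other two stromal genes tested, THY1 and COL1A1, did not pass over all genes (adjusted p = 0.0675 and 0.683), although THY1 passed adjusted over the list alone (0.026).

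Messages of the mitochondrial genome moved in both directions. MT-CO1, a subunit of cytochrome c oxidase (mitochondrial positions 5904 to 7445), fell from 8340 ± 359 to 5661 ± 160 RPKM (n = 3 each, log2 fold change −0.56, limma adjusted p = 0.000576). MT-ND5, a subunit of complex I (12337 to 14148), rose from 3619 ± 124 to 4409 ± 65 RPKM (log2 fold change 0.29, adjusted p = 0.00283), and MT-ND6 and MT-ATP8 changed by 0.26 and −0.17. MT-ND6 lies on the opposite strand directly after MT-ND5. Without a known strand setting, its reads may include some running on from MT-ND5, so these rises may not be separate. Of 13 mitochondrial messages, 3 rose and 2 fell, and the list did not move one way (camera adjusted p = 0.541). Under quantile normalization, which assigns the most abundant genes a value by rank, MT-CO1 lost its call (−0.08, adjusted p = 0.412) and MT-ATP8 turned to 0.08 (adjusted p = 0.412). The share of reads on mitochondrial messages was 8.15% ± 0.0544 in BPP and 8.64% ± 0.301 in control, with every BPP library below every control library (n = 3 each, two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). The share of all reads on mitochondrial genes was 10.9% ± 0.127 in BPP and 11.2% ± 0.419 in control (n = 3 each, two-sided exact permutation p = 0.4).

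**Figure D4:**
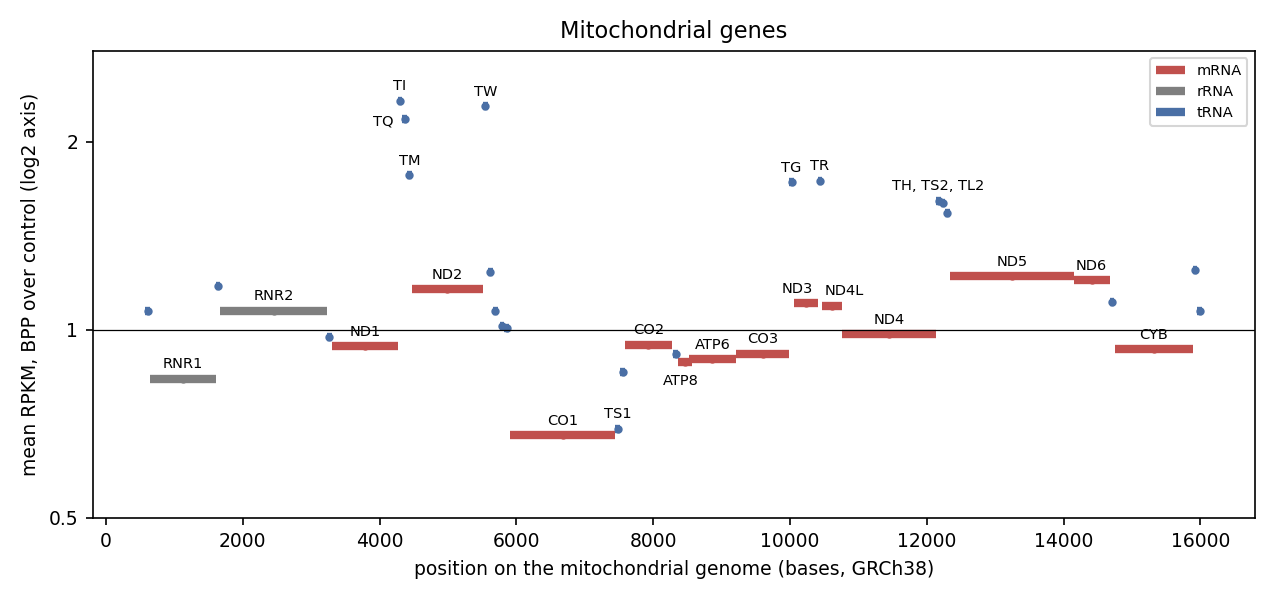
Ratio of mean RPKM, BPP over control (log2 axis), for each mitochondrial gene against its position on the mitochondrial genome in bases. Bars span mRNA (red) and rRNA (grey) genes and blue points are tRNA genes, each a ratio of means over 3 libraries per group; MT-CO1 lies lowest at 0.679 and MT-TI highest at 2.33.

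Whether reads were counted by strand is not given in the sources used here. Of 145 genes considered for naming, 31 share at least 100 exonic bases with another listed gene whose mean RPKM is at least 50% of their own, so their values are uncertain. Among those named above these are HLA-DMB, HCST, FAM72B, FADS2, DDIT4, CLSPN, KIF2C, FAS, VEGFA, ALDOC, SLC16A3, FDPS, ACLY, VIM, RAD54B, CD68 and THY1.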

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

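The voom, protein-coding and GC settings were chosen after seeing the data. The 3033 calls became 852 without a filter on low genes (392 higher, 460 lower), where 40021 genes were tested and 791 of the 3033 were kept, and HDAC1 lost its call, leaving 0 study genes in place of 1; the cause was not tested. Leaving out 1 library gave 1646 to 2485 calls, 802 to 1427 higher and 844 to 1058 lower, from fewer samples. With voom on the recovered reads 2516 genes were higher (4522 in all), and with median-ratio rescaling 2263 were lower (4515 in all), from 21301 genes tested; this cause was also not tested. Counts stayed between 2302 and 3475 under the other settings, and median-ratio rescaling gave more lower than higher genes (1416 higher, 1603 lower). Main calls that could be tested kept their direction in all 18 settings except 2 of 3033 under quantile normalization. Camera with an estimated correlation passed 0 lists (1, the HDAC-inhibitor-induced list, at an unadjusted p of 0.0498), against 10 with the preset one and 11 with fry; single libraries left out gave 8 to 11. MT-ATP8 turned to 0.080 under quantile normalization, by its construction from ranks. Of 24 genes named for the largest changes, 23 kept their call in every setting where they were tested. Across the named genes 2390 of 2541 values stayed on their side of the threshold, 137 lost and 13 gained a call; for lists tested with the preset correlation these were 519 of 533, 6 and 8. The gains were in the mesenchymal (3), YAP and TGF-beta, endoplasmic reticulum chaperone, heat-shock, class I deacetylase and ovarian marker lists, and the losses in the replication (4) and HDAC-inhibitor-induced (2) lists. With fry the ribosomal protein and replication lists lost their call, and the class I deacetylase, heat-shock and mesenchymal lists gained one. With the replicate number as a replicate block the count was 2393. Same-numbered libraries did not deviate together (correlations 0.016, −0.014 and −0.017, own number highest only for replicate 1). These values gave no sign that the numbers pair the samples, but 3 libraries per group cannot exclude it. The settings meant for counts, for a table holding both units and for annotated terms were not run, since the table has RPKM and no terms. Depth limits genes as low as BIN2, which has 12 to 30 reads per library.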

Other observations

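All tests of explanations here were chosen after the data had been seen, those on GC content and gene length and on mitochondrial RNA processing factors before their own outcome was known. Reads over mitochondrial transfer RNA (tRNA) genes showed some of the largest rises in the data. These genes are 59 to 75 bases long and the libraries were made for mRNA. Whether such reads came from mature tRNA or from longer transcripts over these positions was not tested, so the values are not tRNA levels. MT-TI, MT-TQ, MT-TM and MT-TW, which flank MT-ND2, were 2.33-fold, 2.18-fold, 1.77-fold and 2.28-fold higher in BPP by mean RPKM. MT-TG and MT-TR, on either side of MT-ND3, were 1.72-fold and 1.73-fold higher, and MT-TH, MT-TS2 and MT-TL2, directly before MT-ND5, 1.61-fold, 1.6-fold and 1.54-fold. These 9 genes, grouped after their values were seen, all passed the limma test, while of the other 13 mitochondrial tRNA genes 4 rose and 2 fell. MT-TS1, on the opposite strand next to the 3′ end of MT-CO1, fell to 0.694 of control beside 0.679 for MT-CO1. Without a known strand setting, reads running on from MT-CO1 may be counted for MT-TS1, so the falls may not be separate. The share of reads on mitochondrial tRNA genes was 0.198% in BPP and 0.169% in control.

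A change in the share of mitochondrial RNA would move its messages alike. With each library centred on the mean of all 13 messages, their log2 changes had an SD of 0.23 against 0.033 expected from the replicate spread, so such a change is not the whole cause; this value restates that the messages moved apart, and a shared change on top of it stays open. The share of reads on small nuclear-encoded RNA was lower in each BPP library than in each control (difference −0.00527 percentage points). This gave no sign of more short RNA kept in the BPP libraries. Some of these small RNA genes share exonic bases with longer genes, such as SNORD57 with NOP56, which fell. The share can follow such genes, so it cannot decide the question. Of 24 tested mitochondrial RNA processing factors, a list that also holds transcription factors such as TFAM and POLRMT, 4.17% passed. Among all genes 21.7% passed (Fisher's exact p = 0.0434). At this threshold, that argues against changes in their messages being more frequent than among all genes. Fisher's test treats genes as independent, and a gene that did not pass may still have changed. The 1 factor that passed, GRSF1, fell from 13 ± 0.253 to 11.3 ± 0.723 RPKM, 0.874 of control. Others came near the threshold in both directions. FASTKD5 was at 0.886 of control (limma adjusted p = 0.0869), HSD17B10 at 0.941 (0.0888) and KIAA0391 at 1.06 (0.11). An effect of GRSF1, of factors that did not pass, or of proteins without a change in message stays open as an untested biological explanation. Reads shared with nuclear copies of the mitochondrial genome were not tested.

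The 5 lower lists with the smallest camera p, for lipid synthesis, hypoxia, glycolysis, ATF4 and CHOP targets and immediate-early genes, hold 137 different tested genes, of which 94 fell and 0 rose at adjusted p 0.05 in limma. After correction for GC content and gene length, which also removed a trend with mean expression, all 5 lists remained lower. They also stayed past the threshold in camera with the preset correlation. This argues against a bias with GC content or gene length as the whole cause. With an estimated correlation none of the 5 lists passed in the main data (camera adjusted p 0.406 to 0.525). A candidate explanation is lower output of mTORC1, the growth-regulating kinase complex, whose known targets include sterol, glycolysis, pentose phosphate and ATF4 genes. Of 9 pentose phosphate genes only 2, PGD and TKT, fell and 1, PRPS1, rose, and TKT lost its call without BPP replicate 1 (limma adjusted p = 0.0512), without BPP replicate 3 (0.051) and without a filter on low genes (0.0802); 2 of 9 meets the bound set against the hypothesis, but a requirement added after this value was seen, that the exact binomial interval (2.81% to 60%) exclude 50%, was not met, so the hypothesis stays open. A difference between culture dishes, such as cell density or oxygen, cannot be told apart from the peptide, because no label ties libraries to dishes; the mitosis list rose at the same time (median log2 change 0.10), and no value bears on which of these applies.

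The number of called genes was compared with the other ways to split the 6 libraries into 3 and 3. The real split gave 3033 genes by limma and the highest of the other 9 gave 0. At an unadjusted p under 0.05 the other 9 gave 283 to 438 genes, against 5176. Each of the other 9 splits mixes BPP and control libraries. A real group difference then adds to the spread within each set and lowers the count. These splits are thus no fair measure of chance, and no conclusion is drawn from them. Besides, 1 of the 10 splits gave as many genes as the real one, namely itself, and 10 splits are too few for a share under 0.05. Log2 changes were related to GC content across genes (Spearman −0.18) and weakly to length (0.088), though genes are not independent replicates. After removal of both trends, fitted together with a trend with mean expression, 2961 genes passed, and 2583 of 2999 called genes kept their call. This argues against a bias with GC content or length as the whole cause of the count.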
